A study of Schizosaccharomyces pombe with 24 samples.

How the data were processed

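Small RNA was sequenced from fission yeast cells after removal of nitrogen. The labels give 4 strains (wild type, ago1D, clr4D and dcr1D, where D stands for a deletion) at 0, 1, 2, 4, 10 and 24 h, with 1 library for each strain and time, 24 in all. Per the submitters' processing notes, adapters were removed with cutadapt (version not given in the sources used here), reads were aligned with Bowtie2 2.1.0 to the ASM294v2 assembly, and reads were counted per annotated transcript with HTSeq 0.6.1. The deposited values are raw counts per transcript, 1 file per library, with 6878 features. The strand setting of the counting is not given in the sources used here. It was read from the counts, because HTSeq sets aside as ambiguous a read that fits more than 1 feature. Of 389 features whose exons lie, with a margin of 50 bases, wholly within exons of other counted features on the other strand, 377 had a count, against 1 of 20 lying so within exons on the same strand. Counting therefore kept the strands apart, and nuclear tRNA genes held 16.7% of gene counts in wild type at 0 h. Which strand was taken as sense is not stated.

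Each file ends with 5 HTSeq summary lines, which were kept out of library sizes and tests. Of the reads in a file, 67.3% to 97.4% (mean 90.5%) were set aside by HTSeq for low mapping quality, 0.459% to 7.08% fell in no feature and 0.048% to 0.957% were ambiguous between features. Genes received 1.27% to 25.2%, or 117245 to 2121235 counts per library (mean 468000, SD 392000), out of 2512460 to 14834721 reads. Bowtie2 gives reads with several equal placements a low mapping quality, so the tables say little about repeated sequence.

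Feature identifiers were matched to the supplied ASM294v3 annotation, which is not the assembly the authors used, for names, gene classes and overlaps alone. Of 6878 features, 6721 (97.72%) matched. They comprised 5106 protein-coding genes, 1526 non-coding RNAs, 171 nuclear and 25 mitochondrial tRNAs, 10 snoRNAs and smaller classes. No rRNA feature was present, and 307 features had no count in any library. No pair of libraries was identical.

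The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation (factors 0.568 to 1.603) and edgeR's low-count filter by strain (minimum count 10), which kept 4220 genes. Strains were compared with terms for strain and time, so that libraries were matched by time (6 per strain); times were compared with the same terms (4 libraries per time). Late times (10 and 24 h, 2 libraries per strain) were compared with the 4 earlier times within each strain, and interactions tested whether that difference departed from wild type. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in a contrast. Adjusted p values below are from edgeR for genes. For gene lists they are from camera of limma 3.58.1 with a preset correlation of 0.01, repeated with an estimated correlation and with fry. The biological coefficient of variation was 0.297 for strains and times and 0.391 for late times. The labels do not state whether the libraries of a strain came from separate cultures, so p values measure the spread between these libraries only.

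The contrasts, tests, gene lists and the rule for named genes were fixed before the data were examined. Under that rule the genes named were the 10 largest rises and 10 largest falls that passed in each strain contrast against wild type, in 24 h against 0 h and in late against early wild type, with a mean log2 CPM above 3 and the same sign at all 6 matched times (or in all 4 strains, or with every late library beyond every early one). For contrasts between deletions and for interactions they were the 5 of smallest adjusted p in each direction. For each gene list they were up to 4 members of smallest adjusted p, whether or not they passed. The genes ago1, clr4 and dcr1 were named throughout. Any other gene named was chosen after its values were seen. The lists of mating-type genes had the receptors mam2 and map3 exchanged; corrected lists and a list of sporulation genes were added after values were seen.

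Ratios of pooled counts with a 95% exact interval stand in place of fitted fold changes for SPNCRNA.231, SPNCRNA.232, SPNCRNA.359 and tlh2 wherever a strain held 6 counts or fewer over its 6 libraries, and for SPNCRNA.770 and SPNCRNA.1005, with 3 counts or fewer in wild type. This treatment was chosen after their values were seen. Where the strain held none, a lower bound was set at 3 counts over the group. Other genes with few wild-type counts kept fitted fold changes. Intervals and floors cover counting error only. Shares of gene counts by class and region were compared between matched times with an exact two-sided sign-flip test over 64 sign patterns, whose smallest p is 0.031. The scripts were tested on simulated data of 4220 genes, 100 changed per fold size. For ago1D against wild type, 49% of genes changed 2-fold and 92% of those changed 4-fold were recovered, and for 24 h against 0 h 21% and 85%. For late against early wild type 10% and 78% were recovered, and for the dcr1D interaction 1% and 16%. All counts were simulated with the spread of the fit of strains and times (biological coefficient of variation 0.297). The late fit had 0.391, so the simulations may overstate recovery for the late comparisons and the interaction.

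The alternatives tried were DESeq2 1.42.0 (size factors, and its Wald test), total counts without TMM, no low-count filter, tRNA genes left out, a minimum change of 2-fold, models without the term for time or strain, only the libraries compared, a slope over time, a time factor, 0 h left out, and each time or strain left out in turn. Chosen after seeing the data were refits without the libraries labelled ago1D 0 h and 2 h, without those labelled ago1D 0 h, 1 h and 2 h, and without those labelled clr4D 10 h and dcr1D 10 h. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for shares, bounds and plots. Sequence reads were not analysed here, so read length and repeats were not examined.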

Results

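Small RNA was measured in Schizosaccharomyces pombe cells moved to medium without nitrogen, where they stop dividing and become quiescent. The series asks how small RNAs bound by Argonaute direct the heterochromatin methyltransferase Clr4 to genes in such cells. The wild type, an h+ (P) strain, stood beside strains labelled as lacking ago1 (Argonaute), clr4 or dcr1 (Dicer). Each strain had 6 libraries, at 0, 1, 2, 4, 10 and 24 h, so no strain and time had a replicate. Gene counts per library ran from 188998 to 640322 in wild type, 117245 to 674555 in ago1D, 202385 to 634379 in clr4D and 187143 to 2121235 in dcr1D.

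The deleted genes were examined first. ago1 had 11 to 35 counts per wild-type library and 0 to 8 per library labelled ago1D, a log2 fold change of -2.80 (SE 0.29, adjusted p = 1.06e-06). clr4 did not fall in the libraries labelled clr4D: it had 25 to 85 counts there and 9 to 31 in wild type, and rose by 1.36 (SE 0.22, adjusted p = 0.00193). dcr1 had 23 to 79 counts per library labelled dcr1D and 16 to 37 in wild type, with a log2 fold change of 0.04 (SE 0.22). The labels do not give the deleted part of each gene. The counts of clr4 and dcr1 therefore do not bear out these labels, and "the libraries labelled clr4D" or "dcr1D" is meant wherever those strains are named below.

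Time labels were compared through profiles: the mean-centred gene profile of each library was correlated over genes with a mean profile of other strains at each time. The ago1D libraries were left out of every such mean. Libraries of ago1D were thus compared with wild type, clr4D and dcr1D, and libraries of those strains only with one another's strains. All 18 libraries of wild type, clr4D and dcr1D were closest to their own time, against 3 of 6 of ago1D. The library labelled ago1D 0 h had r = 0.615 with the others at 1 h and -0.155 with those at 0 h. The library labelled ago1D 1 h had r = 0.44 with 2 h and 0.307 with 1 h, and that labelled ago1D 2 h had 0.839 with 0 h and -0.427 with 2 h. Genes are not independent replicates, so these values carry no p.

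**Figure D1:**
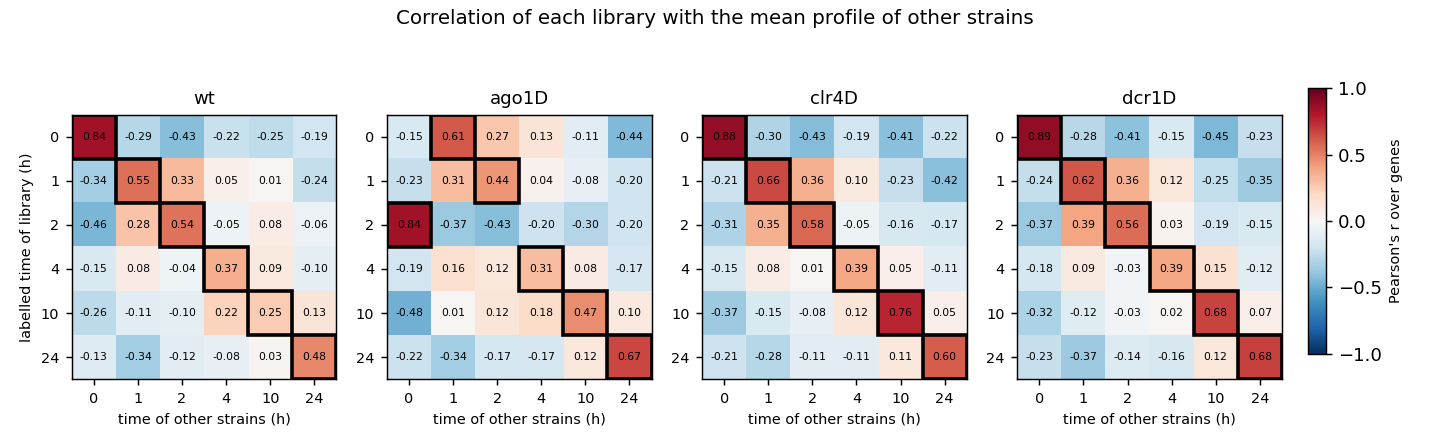
Pearson's r over genes (colour and printed value) between each library (vertical axis, labelled time in h) and the mean profile of the other strains at each time (horizontal axis, h), 1 panel per strain. The ago1D libraries were left out of every mean profile. A black box marks the closest time: it lies on the diagonal in 18 of 18 libraries of wild type, clr4D and dcr1D and in 3 of 6 of ago1D.

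The comparison of ago1D with wild type asks which small RNAs depend on Argonaute. Small RNA of the pericentromeric non-coding RNAs SPNCRNA.359 and SPNCRNA.232 was nearly absent without ago1. SPNCRNA.359 had 1123 counts over the 6 wild-type libraries and 0 over the 6 ago1D libraries, so it was at least 489-fold lower. SPNCRNA.232 had 2652 and 1, a ratio of 3470 (95% interval 622 to 137000). The wild-type library at 0 h held 701 of the 1123 and 1938 of the 2652 counts, and without 0 h SPNCRNA.359 was at least 211-fold lower and the ratio of SPNCRNA.232 was 1070 (192 to 42400). The largest rise was in SPCC13B11.02c, an uncharacterised reading frame that lies within the annotated antisense transcript of the alcohol dehydrogenase gene adh1. It rose 63.7-fold (log2 5.99, SE 0.37, adjusted p = 1.57e-10), from 35.4 ± 28.2 to 2160 ± 1260 normalised CPM (SD, n = 6), while adh1 itself did not pass (0.23). dip5, an amino acid permease, rose by 4.78 (SE 0.56, adjusted p = 6.25e-06) from 6 to 227 counts.

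Of 4220 genes, 182 differed between ago1D and wild type, 129 higher and 53 lower. Without the libraries labelled ago1D 0 h, 1 h and 2 h, a set chosen after seeing the data, 333 differed (215 higher, 118 lower), and 160 of the 182 were among them. That fit tested 4735 genes in place of 4220. With total-count scaling the split was 130 higher and 22 lower, and all genes moved up by a median of 0.15. The count ran from 79 without the 4 h libraries to 330 without those labelled 2 h.

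Of 17 core stress genes 8 rose in ago1D, none fell and 9 did not pass (also 8 and 0 adjusted over the list alone; list adjusted p = 1.03e-07 and adjusted p = 0.0966 with an estimated correlation). They included the heat-shock chaperones hsp16 (4.69, SE 0.42, adjusted p = 1.27e-07) and hsp104 (1.81, SE 0.22, adjusted p = 1.14e-05) and the cation pump cta3 (3.89, SE 0.42, adjusted p = 2.1e-06). The heat-shock gene ssa1, chosen after its values were seen, rose by 2.54 (SE 0.24). Of 9 genes of the phosphate and iron regulons, 4 rose and 1 fell (the same adjusted over the list alone; list adjusted p = 0.00265, and adjusted p = 0.0422 with an estimated correlation). The iron oxidase fio1 rose by 2.08 (SE 0.27) and the iron permease fip1 by 1.29 (SE 0.18), while the phosphate transporter pho84 fell by 1.37 (log2 -1.37, SE 0.24).

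Among 27 pericentromeric features 3 fell and none rose in ago1D (0 and 4 adjusted over the list alone; list adjusted p = 9.18e-06 and adjusted p = 0.0422 with an estimated correlation). SPNCRNA.231 had 137 counts in wild type and 4 in ago1D, a ratio of 44.8 (17.1 to 167), or 22.5 (8.36 to 85.4) without 0 h. Of 140 non-coding RNAs 24 rose and 8 fell (36 and 13 adjusted over the list alone, adjusted p = 0.00012 and adjusted p = 0.091 with an estimated correlation). SPNCRNA.770, of which 89.4% overlaps the nucleolar gene gar2, had 110 counts in ago1D and 3 in wild type, a ratio of 28.0 (9.35 to 138). SPNCRNA.1005, of which 93.6% overlaps hca4, had 69 and 2, a ratio of 26.4 (7.03 to 222). Of 9 snoRNAs 3 rose and none fell (7 and 1 adjusted over the list alone, adjusted p = 0.000116 and adjusted p = 0.309 with an estimated correlation), with snR90 at 1.99 (SE 0.34). Of 25 mitochondrial tRNAs 4 fell and none rose (the same adjusted over the list alone, adjusted p = 6.71e-07 and adjusted p = 0.444 with an estimated correlation).

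The subtelomeric helicase gene tlh2 had 26 counts in wild type and 0 in ago1D, so it was at least 11.3-fold lower. SPBC530.02, a predicted membrane transporter, also fell (-3.22, SE 0.51, adjusted p = 0.000335). SPNCRNA.1443 fell by 1.53 (SE 0.26) and the borate transporter bor1 by 1.39 (SE 0.23, adjusted p = 0.000467). wtf17 (-1.77, SE 0.46, adjusted p = 0.0285) and the splicing factor cwf12 (-1.41, SE 0.36, adjusted p = 0.0275), of which 91.3% overlaps gtb1, no longer passed with total-count scaling or without the libraries labelled ago1D 0 h, 1 h and 2 h. Further rises were those of SPAPB24D3.07c (5.08, SE 0.63), which lies within SPNCRNA.865 on the other strand, SPCC737.04 (3.73, SE 0.34) and mug108 (3.49, SE 0.45), which lies within rga3.

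The comparison of clr4D with wild type asks which small RNAs depend on the methyltransferase. Transcripts of mating type M rose in these libraries although the wild type is of type P. mfm1, mfm2 and mfm3, which encode the M-factor pheromone, rose by 5.96 (SE 0.58, adjusted p = 5.04e-07), 5.38 (SE 0.45, adjusted p = 4.38e-08) and 6.58 (SE 1.18, adjusted p = 0.00354). mam2, the P-factor receptor of M cells, rose by 5.20 (SE 0.63, adjusted p = 2.11e-05). Wild-type counts over 6 libraries were only 8, 5, 6 and 6 for these genes, and 954, 299, 1476 and 461 in clr4D. The M-factor genes are related copies, so their reads are hard to assign.

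Small RNA of the same pericentromeric non-coding RNAs fell in clr4D: SPNCRNA.232 fell by 4.95 (SE 0.40, adjusted p = 3.23e-08) and SPNCRNA.231 by 2.93 (SE 0.50, adjusted p = 0.00221). SPNCRNA.359 had 4 counts against 1123 in wild type, a ratio of 333 (130 to 1230), or 142 (54.9 to 522) without the 0 h libraries. Of 27 pericentromeric features 3 fell and none rose (0 and 4 adjusted over the list alone, adjusted p = 0.000265 and adjusted p = 0.0622 with an estimated correlation). tlh2, with sequence related to the centromeric repeats, moved the other way, with 97 counts in clr4D and 26 in wild type (1.80, SE 0.35, adjusted p = 0.0138), and did not pass without the 1 h, 4 h or 10 h libraries. Of 35 subtelomeric features 2 rose and none fell (2 and 3 adjusted over the list alone, adjusted p = 0.274).

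SPCC13B11.02c rose by 3.52 in clr4D (SE 0.34, adjusted p = 5.04e-07), to 422 ± 279 normalised CPM (SD, n = 6). SPAPB24D3.07c rose by 3.92 (SE 0.66) and mug24 by 2.47 (SE 0.42). The non-coding RNAs SPNCRNA.724 (2.68, SE 0.49), SPNCRNA.1206 (2.58, SE 0.46) and SPNCRNA.857 (2.47, SE 0.48) rose, each overlapping a gene on the other strand (prp22, nup211 and SPACUNK4.17). None of these 3 passed without the 24 h libraries, nor did mug24, pyp2 or hsp16. Of 17 core stress genes 3 rose and none fell (the same adjusted over the list alone, adjusted p = 0.0013 and adjusted p = 0.429 with an estimated correlation): cta3 (2.82, SE 0.42), the tyrosine phosphatase pyp2 (2.09, SE 0.37) and hsp16 (2.29, SE 0.42). In all, 38 genes differed, 35 higher and 3 lower. There were 149 (121 and 28) without the libraries labelled ago1D 0 h, 1 h and 2 h, and 31 without clr4D 10 h and dcr1D 10 h, both chosen after seeing the data. The count ran from 10 without the 24 h libraries to 76 without those labelled 0 h.

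The comparison of dcr1D with wild type asks which small RNAs depend on Dicer. SPCC13B11.02c rose by 6.57 (SE 0.38, adjusted p = 6.08e-11), to 3680 ± 2730 normalised CPM (SD, n = 6). Small RNA of the same pericentromeric non-coding RNAs was nearly absent: SPNCRNA.359 had 1 count against 1123, a ratio of 1930 (345 to 76200), and SPNCRNA.232 had 6 against 2652, a ratio of 759 (348 to 2070). SPNCRNA.231 had 2 against 137 (118, interval 32.0 to 981), and tlh2 had 1 against 26 (44.7, interval 7.34 to 1830). Without the 0 h libraries these ratios were 637, 216 and 45.3, and tlh2, with 0 counts left in dcr1D, was at least 8.06-fold lower. Of 27 pericentromeric features 4 fell and none rose (1 higher and 4 lower adjusted over the list alone, adjusted p = 0.000107 and adjusted p = 0.113 with an estimated correlation).

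M-cell transcripts rose in dcr1D as in clr4D: mfm1 by 5.78 (SE 0.58), mfm2 by 4.91 (SE 0.46), mfm3 by 6.06 (SE 1.18) and mam2 by 4.57 (SE 0.65). On the corrected list of M-cell genes 4 of 5 rose in each of clr4D and dcr1D (5 adjusted over the list alone). For the list as fixed, in which 3 of 5 rose in each (5 adjusted over the list alone), the adjusted p was 1.6e-08 in clr4D and 3.92e-06 in dcr1D, and adjusted p = 0.0611 and 0.169 with an estimated correlation. In ago1D none of the 5 passed (adjusted p = 0.845).

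Of 17 core stress genes 5 rose in dcr1D and none fell (adjusted p = 0.000107 and adjusted p = 0.436 with an estimated correlation), with hsp16 at 3.70 (SE 0.42, adjusted p = 4.66e-06) and cta3 at 3.87 (SE 0.42, adjusted p = 3.08e-06). SPAPB24D3.07c rose by 4.72 (SE 0.63) and mug108 by 3.32 (SE 0.44). Of 35 subtelomeric features 1 rose and 4 fell (2 and 5 adjusted over the list alone, adjusted p = 0.0023 and adjusted p = 0.512 with an estimated correlation). Further falls were those of SPCTRNAPHE.05 (-2.93, SE 0.69), cms1 (-1.43, SE 0.36), the predicted transporter SPBC1271.10c (-1.30, SE 0.26), the cyclin puc1 (-1.19, SE 0.28) and pho84 (-1.19, SE 0.24), which did not pass without the 4 h, 10 h or 24 h libraries. In all, 107 genes differed, 79 higher and 28 lower. The count was 466 (314 and 152) without the libraries labelled ago1D 0 h, 1 h and 2 h, and 53 without clr4D 10 h and dcr1D 10 h, both chosen after seeing the data. It was 54 (34 and 20) with total-count scaling, and ran from 33 without the 4 h libraries to 190 without those labelled 0 h.

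**Figure D2:**
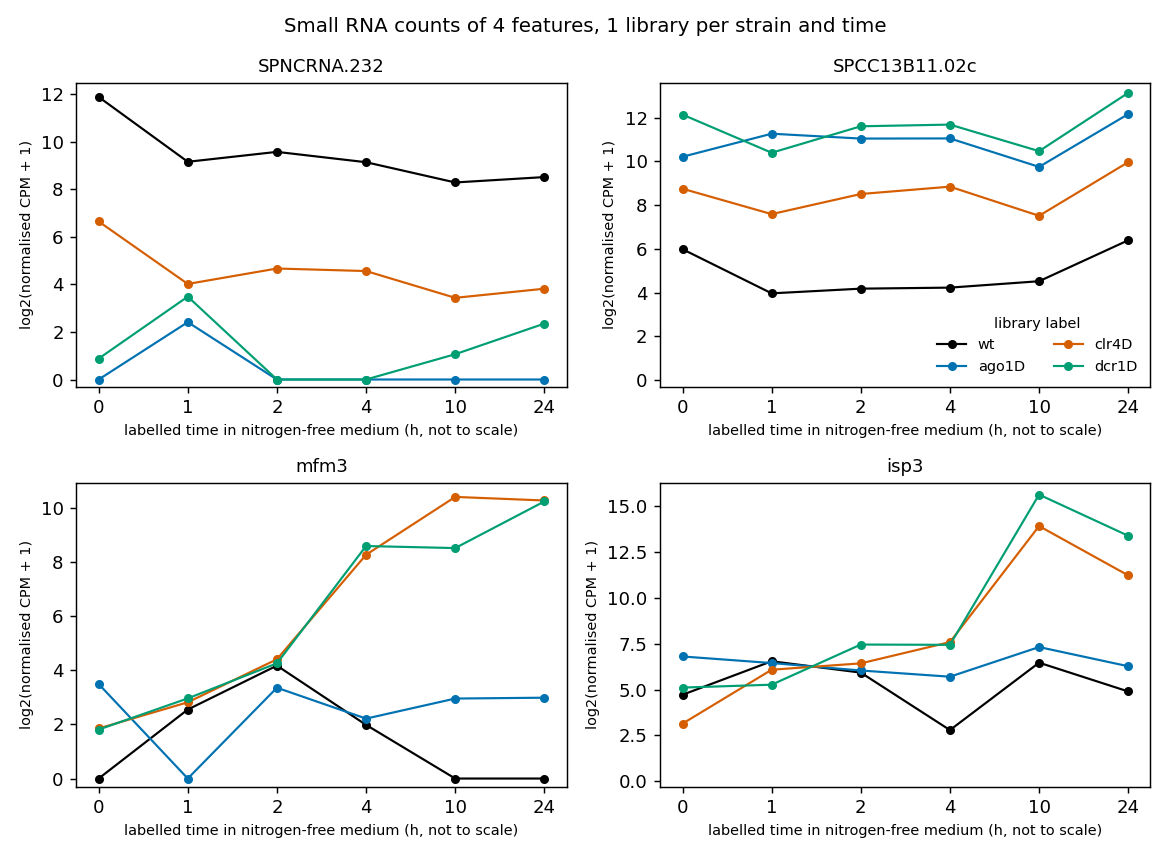
Small RNA of SPNCRNA.232, SPCC13B11.02c, mfm3 and isp3 as log2 of normalised CPM plus 1 (vertical axis) by labelled time in h (horizontal axis, not to scale), 1 library per point and 1 line per strain. Wild type is highest for SPNCRNA.232 and lowest for SPCC13B11.02c at each labelled time, and isp3 is highest in dcr1D at 10 h, with 47020 counts.

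The 3 strains share wild type as control, which alone makes their contrasts move together. Above wild type in all 3 stood 15 genes, among them SPCC13B11.02c, hsp16, cta3, ssa1, pyp2, mug24 and SPAPB24D3.07c, and below it stood the 3 non-coding RNAs SPNCRNA.231, SPNCRNA.232 and SPNCRNA.359. Between ago1D and dcr1D 42 genes were higher in both and 17 lower in both, between clr4D and dcr1D 24 and 3, and between ago1D and clr4D 20 and 3. Over genes, which are not independent replicates, fold changes correlated with r = 0.713, 0.794 and 0.684 for these pairs, and with 0.526, 0.528 and 0.512 in 20 simulations with no strain difference, through the shared control alone. In the simulations no gene was called in both members of a pair. The mean number called was 0.1 in ago1D and 0 in clr4D, so hardly any overlap could have arisen. Each member of a pair was also given separate wild-type controls (3 libraries each, both ways). Then 12 and 9 genes were higher in both ago1D and dcr1D, and 5 and 6 in both clr4D and dcr1D. In both ago1D and clr4D 5 and 2 were higher. Fold changes then correlated with r = 0.54 and 0.443, 0.545 and 0.493, and 0.461 and 0.404 for these pairs.

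Deletion strains were also compared directly. ago1D and dcr1D differed in 39 genes (19 higher and 20 lower in ago1D; 41 and 13 with total-count scaling), ago1D and clr4D in 45 (27 and 18; 46 and 15), and clr4D and dcr1D in 6 (4 and 2; 4 and 1). With only the 12 libraries compared these counts were 3, 10 and 145 (52 and 93), the last with 4 of the 6 among them. With DESeq2 they were 69, 61 and 20 (3 and 17), the last with 2 of the 6 among them. Without the libraries labelled ago1D 0 h, 1 h and 2 h these were 158, 112 and 37, and without clr4D 10 h and dcr1D 10 h the first 2 were 10 and 24, all chosen after seeing the data. mfm1 was lower in ago1D than in dcr1D (-6.11, SE 0.58, adjusted p = 6.98e-07) and than in clr4D (-6.29, adjusted p = 2.65e-07), and so was the transporter SPBC530.02 (-4.30 and -4.16, SE 0.48 each). SPCC13B11.02c was lower in clr4D than in dcr1D (-3.06, SE 0.31, adjusted p = 4.41e-06), and hsp16 was higher in ago1D than in clr4D (2.39, SE 0.36, adjusted p = 0.000351). SPNCRNA.232 had 68 counts in clr4D and 6 in dcr1D, a ratio of 16.4 (interval 7.16 to 46.2), but its test (adjusted p = 0.00556) did not pass without the time term or without the 0 h, 4 h or 10 h libraries. tlh2 had 97 counts in clr4D, 1 in dcr1D (a ratio of 140, interval 24.6 to 5600) and 0 in ago1D (at least 35.6-fold).

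The comparison of 24 h with 0 h, over all 4 strains, asks how small RNA changed as cells became quiescent. Mitochondrial RNA fell: all 25 mitochondrial tRNAs fell (the same adjusted over the list alone; list adjusted p = 3.77e-25 and adjusted p = 0.145 with an estimated correlation), led by SPMITTRNAARG.01 (-4.79, SE 0.57, adjusted p = 4.86e-06). All 8 other mitochondrial features fell too (adjusted p = 1.75e-07 and adjusted p = 0.173 with an estimated correlation). Of 140 non-coding RNAs 75 rose and 3 fell (83 and 4 adjusted over the list alone, adjusted p = 1.47e-15), which held with an estimated correlation (adjusted p = 0.00094). Of 9 snoRNAs 8 rose and none fell (adjusted p = 1.75e-07 and adjusted p = 0.147 with an estimated correlation), with snR30 at 3.52 (SE 0.39, adjusted p = 2.74e-06). The library labelled ago1D 0 h is 1 of the 4 libraries at 0 h.

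Single genes with large rises at 24 h were the dihydroxyacetone kinase dak2 (5.39, SE 0.64, adjusted p = 4.86e-06), SPAC869.04 (5.18, SE 1.04) and SPAC5H10.04 (4.24, SE 0.50), of which 97.6% overlaps SPAC5H10.05c. The non-coding RNAs SPNCRNA.1364 (3.97, SE 0.67), SPNCRNA.865 (3.93, SE 0.42) and SPNCRNA.920 (3.79, SE 0.47) rose as well. The rises of mfm1 (7.39, SE 0.74) and of the kinase shk2 (4.71) rested on clr4D and dcr1D: at 24 h mfm1 had 286 and 195 counts there, 2 in wild type and 1 in ago1D, and shk2 had 41, 45, 3 and 6. The kinase gene ppk26 fell most among protein-coding genes (-4.85, SE 0.55, adjusted p = 2.74e-06).

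Of 14 genes of the nitrogen starvation response 3 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.000888 and adjusted p = 0.314 with an estimated correlation). Those 3 were mei2, an RNA-binding regulator of meiosis (2.70, SE 0.31), the peptide transporter isp4 (2.57) and the mating transcription factor ste11 (1.04), and aes1 fell by 1.80. Of 15 autophagy genes 4 rose and none fell (the same adjusted over the list alone, adjusted p = 0.00515 and adjusted p = 0.41 with an estimated correlation): atg17 (1.54), atg6 (1.58), atg13 (1.31) and atg8 (1.42). Of 35 subtelomeric features 15 rose and 4 fell (18 and 5 adjusted over the list alone, adjusted p = 0.000318 and adjusted p = 0.235 with an estimated correlation), with dak2 and SPAC869.04 among the rises and the acid phosphatase pho1 (-2.38) among the falls. Of 17 core stress genes 4 rose (3 adjusted over the list alone, adjusted p = 0.0121 and adjusted p = 0.394 with an estimated correlation). On the M-cell list as fixed, in which the P-cell gene map3 stood in place of mam2, 4 of 5 genes rose (adjusted p = 0.0279 and adjusted p = 0.394 with an estimated correlation). The rise of mfm1 among them rested on clr4D and dcr1D, as given above. mfm2 and mfm3 had only 5 and 6 counts over the 6 wild-type libraries, and 5 and 17 in ago1D. They had 299 and 1476 in clr4D, and 268 and 823 in dcr1D. At 24 h mfm2 was above 0 h in 4 strains, but mfm3 was above it in 2 and below it in 1.

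Some other groups with lower median values at 24 h depended on the scaling. Of 35 amino acid biosynthesis genes 14 fell and none rose (0 and 15 adjusted over the list alone, adjusted p = 3.02e-05 and adjusted p = 0.233 with an estimated correlation), among them arg4 (-2.07), lys3 (-1.85) and ilv3 (-2.03), but with total-count scaling 9 rose and 5 fell. Of 139 ribosomal protein genes 15 fell and none rose (0 and 4 adjusted over the list alone, adjusted p = 0.00823 and adjusted p = 0.772 with an estimated correlation), but with total-count scaling 44 rose and 2 fell. Of 51 nuclear tRNAs 3 rose and 23 fell (3 and 24 adjusted over the list alone, adjusted p = 3.02e-05 and adjusted p = 0.394 with an estimated correlation), and with total-count scaling 11 rose and 13 fell. The histone genes hht2 (1.68) and hhf2 (1.52) rose and hht1 (-1.64) and hhf1 (-1.05) fell, but with total-count scaling 4 histone genes rose and none fell; these genes are near copies, so reads between them are hard to assign. Of 27 pericentromeric features 6 fell and none rose (adjusted p = 0.0558), but 6 rose and 1 fell with total-count scaling.

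**Figure D3:**
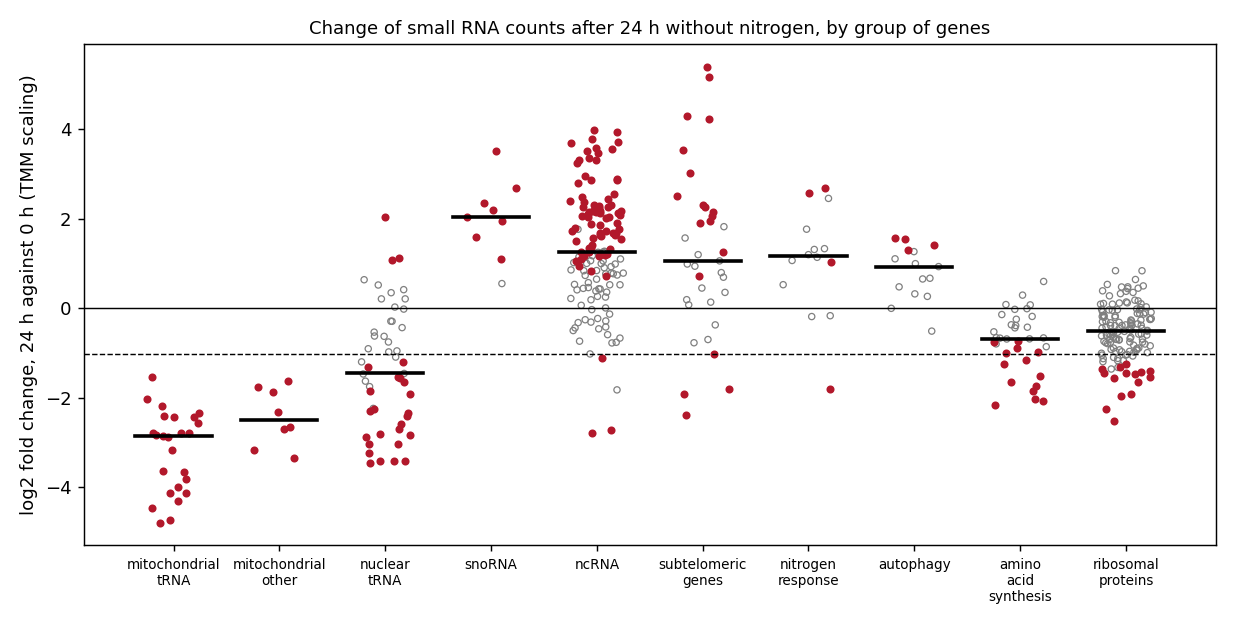
Log2 fold change of 24 h against 0 h (vertical axis) for each gene of the groups named, 1 point per gene, red where it passed and grey open where not, with a bar at the group's median and a dashed line where 0 would lie with total-count scaling. All 25 mitochondrial tRNAs lie below 0 with either scaling in force, while amino acid and ribosomal protein genes change sides: 0 rises and 14 falls become 9 and 5, and 0 and 15 become 44 and 2.

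At 24 h 1224 genes differed from 0 h, 636 higher and 588 lower. With total-count scaling it was 2383 higher and 104 lower, and all genes moved up by a median of 1.03. Without the libraries labelled ago1D 0 h, 1 h and 2 h, chosen after seeing the data, 1991 differed, 1137 higher and 854 lower; without the clr4D libraries 491 did. At 10 h 1229 genes differed (567 higher and 662 lower; 2217 and 130 with total-count scaling), 171 without clr4D 10 h and dcr1D 10 h (chosen after seeing the data) and 138 without the dcr1D libraries. At 1 h 640 genes differed (250 and 390; 123 and 235 with total-count scaling), at 2 h 107 (87 and 20; 361 and 17 with total-count scaling) and at 4 h 399 (145 and 254; 543 and 77). These 3 counts were 1383, 1505 and 1327 without the libraries labelled ago1D 0 h, 1 h and 2 h, and at 1 h and 2 h no gene differed once the libraries of wild type, clr4D or dcr1D were left out. At 4 h 5 did without dcr1D.

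Late times (10 and 24 h) were compared with earlier ones within each strain, which asks whether the deletions change the late response. In wild type 5 genes differed: SPBC19C7.04c (4.09, SE 0.47, adjusted p = 7.16e-05), SPCC569.09 (3.47), lncRNA584 (3.43, SE 0.66), which lies within ski3, and SPAC11D3.19 (2.80, SE 0.53) rose, and cts2 fell (-2.47, SE 0.41). There were 2 without 0 h, 2 without the libraries labelled ago1D 0 h, 1 h and 2 h, and 3 with tRNA genes left out, where the filter kept 3612 genes in place of 4220. In ago1D edgeR found 0 genes, with 231 below an unadjusted p of 0.05. DESeq2 found 30 (3 higher and 27 lower), but gave an adjusted p to only 208 genes. In clr4D 98 differed (89 higher and 9 lower) and in dcr1D 106 (88 and 18). Without clr4D 10 h and dcr1D 10 h, chosen after seeing the data, these were 394 and 61, from 1 late library in each of these strains, whose spread is taken from the other groups. With total-count scaling there were 942 higher and 11 lower, and 419 and 15, with medians of all genes moved up by 0.85 and 0.74.

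Of 17 sporulation genes, a list made after their values were seen and so not independent evidence, 7 rose late in the libraries labelled clr4D and 8 in those labelled dcr1D, and the others did not pass. isp3, a spore wall gene, rose by 6.68 (SE 1.03, adjusted p = 0.00224) in clr4D and 8.22 (SE 1.08, adjusted p = 0.000125) in dcr1D, with 11165 and 47020 counts at 10 h against at most 36 in a wild-type library. agn2, a glucanase that opens the ascus, rose by 4.21 (SE 0.64) and 6.14 (SE 0.67), with 629 and 2729 counts at 10 h and 36 and 84 at 24 h. As a slope over time agn2 did not pass in clr4D (adjusted p = 0.0576). Without clr4D 10 h and dcr1D 10 h, chosen after seeing the data, and so with the 24 h library as the only late one, agn2 rose by 2.19 and 3.90 and isp3 by 4.83 and 6.72. Direct tests of the strain's effect on the late change called no gene with edgeR in ago1D, clr4D or dcr1D, where 128, 283 and 240 genes lay below an unadjusted p of 0.05, and DESeq2 called 0, 2 and 12. For agn2 in dcr1D that test gave 5.86 (SE 1.04, adjusted p = 0.0533) and for isp3 an adjusted p of 0.0936. Without clr4D 10 h and dcr1D 10 h, with 1 late library left in each, the clr4D test called 30 genes. With 2 late libraries per strain, 16% of simulated 4-fold interactions were recovered for dcr1D, with a smaller spread than that of the late fit.

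Lists of genes called in these tests of the strain's effect with a preset correlation were 6 in ago1D, 8 in clr4D and 9 in dcr1D, with no member past the threshold over all genes. With an estimated correlation 0, 1 and 0 remained. The list that remained was the mating-type region in clr4D (median -1.11 over 9 genes, adjusted p = 0.000402, and adjusted p = 0.0182 with an estimated correlation). Ribosomal protein genes had medians of -1.12, -0.98 and -0.99 in ago1D, clr4D and dcr1D (adjusted p = 2.94e-21, 1.68e-13 and 2.23e-15, adjusted p = 0.606, 0.597 and 0.531 with an estimated correlation).

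Shares of gene counts by class and region were compared between strains in 27 exact two-sided sign-flip tests. None passed after adjustment, but 17 of them would have had to reach the smallest possible p for any to pass, so these tests say little on whether shares differ. The pericentromeric share was 2.56% in wild type, 3.8% in ago1D, 2.77% in clr4D and 2.79% in dcr1D. It takes in the tRNA genes of the region and genes in a margin beside it. In wild type at 0 h SPNCRNA.232 and SPNCRNA.359 held 1938 and 701 of its 13987 counts, so this share does not follow their loss. The smallest p that 6 matched times allow, 0.031, was reached by snoRNA, with 1.08% of gene counts in ago1D and 0.488% in wild type (higher at 6 of 6 times; exact p = 0.031, adjusted p = 0.422), and by non-coding RNA, with 5.38% in dcr1D and 6.68% in wild type (lower at 6 of 6 times; exact p = 0.031, adjusted p = 0.422).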

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

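All tests of explanations below were chosen after the results they concern had been seen.

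The libraries labelled ago1D 0 h, 1 h and 2 h lie closest to 1 h, 2 h and 0 h of the other strains. A rotation of these 3 labels was read from these same correlations, so their match to it is no independent support. Each is closer to the rotated time than to its own, by 0.77, 0.133 and 1.27 in correlation. In the other strains no such difference was above -0.228. The smallest stayed between 0.09 and 0.152 in 20 of 20 random thinnings to 113701 counts, which bears on depth alone. An exchange of 0 h and 2 h alone is argued against, since ago1D 0 h is closer to 1 h than to 2 h (-0.344, where other 2 h libraries had 0.168 or more), and a slower response of the strain is argued against by -0.77 for ago1D 0 h, where other 0 h libraries had 1.13 or more. The share of reads of low mapping quality, which does not enter the profiles, was 79.4%, 67.3% and 67.5% at 0 h in wild type, clr4D and dcr1D, 81.0% in the library labelled ago1D 2 h and 93.9% in that labelled ago1D 0 h. The library labelled ago1D 1 h had 97.4%, above the other strains at both 1 h (93.8% to 96.5%) and 2 h (96.0% to 97.0%). An altered early response of the strain that happens to resemble other times was not tested and stays open.

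M-cell transcripts rose at all or most times and spore transcripts late in the libraries labelled clr4D and dcr1D. In cultures of the opposite mating type alone the P-cell genes map2 and map3 should be lost. They were not, with log2 fold changes from 1.21 (map2 in clr4D) to 1.67, none past the threshold. In clr4D the highest library held 248 of 310 counts of map2 and 361 of 422 of map3. The opposite type is not excluded, since cells of that type that also expressed their silent cassettes could keep both genes. Cells of both mating types could be present, but mei3, which cells need both types to express, had 30 counts over these 12 libraries, 0 in wild type and 4 in ago1D, too few to tell. Expression of the silent mating-type cassettes in strains without Clr4 or Dicer could not be told either, since the 4 cassette features had 0 counts and the 9 genes tested around them had a median of -0.26 in clr4D. Mating type was not given for the deletion strains in the labels used here.

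Counts of clr4 and dcr1 were kept in the libraries labelled as lacking them. Whether the labels clr4D and dcr1D were exchanged could not be told: pooled counts of SPNCRNA.232 (ratio of clr4D to dcr1D 16.4, interval 7.16 to 46.2), SPNCRNA.231 (12.3, 2.92 to 110) and tlh2 (140, 24.6 to 5600) speak against it if cells without Dicer hold no more of this small RNA, but clr4 was higher in clr4D than in dcr1D (1.85), where it stood at -0.49. That value is not particular to dcr1D, since clr4 stood at -0.52 (SE 0.25) in ago1D. An exchange would also have dcr1 fall in the libraries labelled clr4D, where it stood at -0.09 (SE 0.22). Undeleted cells are argued against by SPNCRNA.359, whose log2 ratio to wild type was -8.38 or lower in both (-7.15 or lower without 0 h). Reads from parts of the genes left in place could not be told: dcr1 stood at 0.04, while ago1 fell by 2.80 in ago1D. Loss of the coding part alone would give -4.5 for ago1, -1.92 for dcr1 and -0.59 for clr4 under even coverage. None met these values: ago1 fell less (-2.80, SE 0.29), dcr1 did not fall and clr4 rose by 1.36.

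Direct tests flagged differences between deletion strains: 39 genes between ago1D and dcr1D, 6 between clr4D and dcr1D and 45 between ago1D and clr4D. Higher in ago1D than in dcr1D were dip5 (2.84), SPCC737.04 (1.67), SPCC777.03c (2.00), SPAC4H3.08 (1.87) and aah1 (0.88), and lower were mfm2 (-5.27), mfm1 (-6.11), ago1 (-2.81), SPBC530.02 (-4.30) and mam2 (-3.33). Higher in clr4D than in dcr1D were tlh2 (97 counts and 1, ratio 140), clr4 (1.85), SPNCRNA.232 (68 counts and 6, ratio 16.4) and uap2 (1.17), and lower were SPCC13B11.02c (-3.06) and cho1 (-1.48). Higher in ago1D than in clr4D were SPCC13B11.02c (2.47), SPCC737.04 (1.83), hsp16 (2.39), the O-methyltransferase gene cmt1 (1.38) and hsp78 (1.57), and lower were mfm2 (-5.74), ago1 (-3.17), mfm1 (-6.29), SPBC530.02 (-4.16) and tlh2 (0 counts and 97, at least 35.6-fold).

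Reads ambiguous between features, which no comparison used, were flagged as above the wild type. They made up 2.04% of uniquely placed reads in wild type, and 0.894 points more in ago1D, 0.419 in clr4D and 0.81 in dcr1D, higher at 6 of 6 matched times in each (exact two-sided sign-flip p = 0.031, adjusted p = 0.0469). Uniquely placed reads include those in no feature, whose share was 32.5% in wild type and 21.1%, 21.7% and 19.7% in ago1D, clr4D and dcr1D. That lower share alone raises the ambiguous share, and a share relative to gene counts was not compared.

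Counts of calls were set against other divisions of the same libraries. For strains, libraries were swapped within times (32 divisions, the real one included), which are not all divisions of 12 libraries. For ago1D against wild type 3 of 32 called as many genes as the real 182 (highest other 285), so chance cannot be excluded for the count. Those with 285 and 221 calls both swap the libraries labelled 2 h. Only the real division called as many for clr4D (38, highest other 16) and dcr1D (107, 5) against wild type and for clr4D against dcr1D (6, 0). The same held for ago1D against dcr1D (39, 35) and ago1D against clr4D (45, 32). This share, 1 of 32, is under 0.05 but the smallest these divisions allow, and was not adjusted over the counts compared. It argues against chance without excluding it. For times, 35 divisions of 8 libraries were made. Chance cannot be excluded for the counts at 1 h (640, 5 of 35, highest other 850) and 2 h (107, 2 of 35, 1559). Nor can it at 4 h (399, 4 of 35, 686). At 10 h (1229, highest other 1222) and 24 h (1224, highest other 1031) only the real division, 1 of 35, called as many. Chance is not excluded there either, since few of the 35 keep the matching by strain. Of the 35 only 8 exchange libraries within strains, too few for a share under 0.05, and the rest mix strains. Among the 8 the highest others had 198 calls at 4 h, 510 at 10 h and 557 at 24 h, all below the real counts. At 1 h and 2 h they had 850 and 1559, above the real counts. The division with 1559 calls moves both ago1D libraries, which points to a structure of the samples. For lists called with a preset correlation chance cannot be excluded in ago1D (8; 18 of 32; highest other 13), clr4D (7; 9 of 32; 9), dcr1D (7; 8 of 32; 11) or 24 h (12; 4 of 35; 14).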

How the results depend on the processing

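Of the counts of calls and tests compared, 134 stayed within 1.5 times the value reported and 139 did not. Of the values of named genes, 6028 kept direction and side of the threshold, 206 passed only under the alternative, 326 passed no longer and 4 reversed. The cause was not tested for any value below unless stated. Depth limits features with few counts to bounds or wide intervals.

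With total counts in place of TMM, calls were 54 for dcr1D against wild type, 358, 378, 620, 2347 and 2487 at 1, 2, 4, 10 and 24 h, 8, 2, 953 and 434 for late times in wild type, ago1D, clr4D and dcr1D, and 1 for the dcr1D interaction. At 24 h gpm1 (0.17), srp7 (0.74), rpb1 (0.26) and ags1 (0.41) reversed, because all genes moved up by a median of 1.03. DESeq2 size factors gave 1 for the dcr1D interaction. Its Wald test gave 163 (dcr1D against wild type), 69 (ago1D against dcr1D), 20 (clr4D against dcr1D), 323 at 2 h, 21, 30 and 179 late in wild type, ago1D and clr4D, and 2 and 12 for the clr4D and dcr1D interactions. It gave an adjusted p to only 784 genes for clr4D against dcr1D, 2502 at 2 h, and 1430 and 208 late in wild type and ago1D.

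With tRNA genes left out, the low-count filter kept 3612 genes in place of 4220, so genes other than tRNA genes dropped out too. The effects of these changes were not separated. Late calls were then 3 in wild type and 43 in clr4D, and calls for the dcr1D interaction were 1. Without the low-count filter they were 89 (clr4D against wild type), 71 (ago1D against dcr1D), 10 (clr4D against dcr1D), 154 and 173 (late in clr4D and dcr1D) and 1 (dcr1D interaction). With at least 2-fold changes 10 h had 800, fewer by construction.

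Without the time term, calls against wild type were 50, 11 and 22 (ago1D, clr4D, dcr1D), and 3, 3 and 14 for ago1D against dcr1D, clr4D against dcr1D and ago1D against clr4D. With only the 12 libraries compared they were 28 and 18 (ago1D and clr4D against wild type), 3, 145 and 10. Without the strain term 4 h had 256. A slope over time gave 56, 385 and 186 in wild type, clr4D and dcr1D, and 1, 2 and 1 for the interactions. An added time factor gave 7 for the dcr1D interaction. Without 0 h, late calls were 2, 29 and 60 in wild type, clr4D and dcr1D.

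Chosen after seeing the data, the fit without ago1D 0 h and 2 h gave 320, 112 and 442 against wild type, 162, 30 and 117 between deletions, and 1422, 1495, 1320, 1927 and 1899 at 1 to 24 h. Without ago1D 0 h, 1 h and 2 h these were 333, 149, 466, 158, 37, 112, 1383, 1505, 1327, 2002 and 1991, and 2 late in wild type. The first of these fits tested 4525 genes and the second 4735, in place of 4220. The effect of the added genes was not separated. Without clr4D 10 h and dcr1D 10 h calls were 53 (dcr1D against wild type), 10 and 24 (ago1D against dcr1D and clr4D), 171 at 10 h, 1, 394 and 61 (late in ago1D, clr4D and dcr1D), and 30 and 1 (clr4D and dcr1D interactions). That fit leaves 1 late library in clr4D and in dcr1D, assumed to vary like the other groups.

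Lists called with an estimated correlation were 2, 1 and 0 for ago1D, clr4D and dcr1D, 1 at 24 h, and 0, 1 and 0 for the interactions; fry called 5, 4, 4, and 1, 1 and 1 for the interactions.

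Leaving out each time in turn gave 79 to 330 (ago1D), 10 to 76 (clr4D), 33 to 190 (dcr1D), 6 to 95 (ago1D against dcr1D), 3 to 9 (clr4D against dcr1D) and 14 to 68 (ago1D against clr4D). Leaving out each strain in turn gave 0 to 1316, 0 to 1440, 5 to 1169, 138 to 1733 and 491 to 1556 at 1, 2, 4, 10 and 24 h.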

Other observations

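The groups below were fixed before the data were examined unless said, and no explanation was tested here. Of 21 RNAi and heterochromatin factors 7 rose at 24 h against 0 h and none fell (the same adjusted over the list alone; list adjusted p = 0.261). They included arb1 (2.19), hrr1 (1.53) and ago1 (1.52). The telomerase RNA ter1 (2.25) and the RNase P RNA rrk1 (1.17) rose among 3 small structured RNAs (adjusted p = 0.0768). Of 25 cell-cycle genes 2 rose and 3 fell (adjusted p = 0.874), of 15 glycolysis genes 2 rose and 3 fell (adjusted p = 0.346; 10 rose and none fell with total-count scaling), and of 9 phosphate and iron genes 1 rose and 2 fell (adjusted p = 0.565).

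Several groups were called against wild type, most without a member that passed. Ribosomal protein genes had medians of -0.29, -0.34 and -0.34 in ago1D, clr4D and dcr1D (adjusted p = 2.46e-05, 4.25e-05 and 0.00475, and adjusted p = 0.818, 0.814 and 0.884 with an estimated correlation). Glycolysis genes had a median of -0.38 in clr4D (adjusted p = 0.000176 and adjusted p = 0.321 with an estimated correlation) and an adjusted p of 0.0454 in dcr1D (adjusted p = 0.637 with an estimated correlation). Histone genes in dcr1D had an adjusted p of 0.0405 (adjusted p = 0.637 with an estimated correlation). Among 8 other mitochondrial features 1 fell in ago1D (adjusted p = 0.000867 and adjusted p = 0.444 with an estimated correlation). Protein-coding genes as a whole were called lower in clr4D (adjusted p = 0.029 and adjusted p = 0.0305 with an estimated correlation), where their median was -0.02, their mean 0.03, and 26 rose and none fell.

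Autophagy genes and the nitrogen starvation response had no member past the threshold against wild type in ago1D (adjusted p = 0.845 and 0.562) or clr4D (0.616 and 0.62). Of 9 genes of the mating-type region rpt6 (-1.03) and cms1 (-1.31) fell in ago1D (adjusted p = 0.071). Lists of P-cell genes and Tf2 retrotransposons could not be tested, with fewer than 3 genes above the filter.

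Counting kept the strands apart, so uniquely placed reads in no feature can lie outside genes or on the other strand of a gene. Their share, added after values were seen, was 32.5% ± 15.8 (SD, n = 6) in wild type, 21.1% in ago1D, 21.7% in clr4D and 19.7% in dcr1D. It was lower at 5 of 6 matched times in ago1D (exact two-sided sign-flip p = 0.0625, adjusted p = 0.0804) and at 6 of 6 in clr4D and dcr1D (exact p = 0.031, adjusted p = 0.0469 each). This matching takes the labels ago1D 0 h, 1 h and 2 h as given. Without these times the share was lower at 3 of 3 in ago1D, with 27.3% against 39.6% in wild type. The share of all reads set aside for low mapping quality was 92.5% in wild type and 88.3% in dcr1D, lower at 6 of 6 matched times (exact p = 0.031, adjusted p = 0.0469), with 91.9% in ago1D and 89.4% in clr4D (adjusted p = 0.719 and 0.211).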
